A study of Homo sapiens with 6 samples.

How the data were processed

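RNA-seq libraries were made from total RNA of T24 cells that had been transduced with lentivirus and selected with puromycin, with a strand-aware library kit, per the labels' protocols. The 6 libraries fell into 2 groups of 3 by their titles, shControl and shBLACAT3. Per the submitters' processing notes the tools named were cutadapt, HISAT2 2.1.0 and StringTie, with no role or order given, and the genome build, the annotation, the strand setting of the counting and any step between the tools are not given in the sources used here. The values the authors deposited were read as FPKM from the values themselves and from the tools named per the labels, since the file header names no unit: they were not whole numbers, and the columns summed to different totals between 211958 and 226953. No further scaling between libraries is recorded.

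The table held 6 columns of values, headed by the cell line, NC or SH, and a number. NC was read as the control hairpin and SH as the hairpin against BLACAT3, and the number as the replicate of the title. Of 11081 gene rows, 11007 were matched to a symbol through the identifiers of GENCODE 29 (GRCh38) and 74 kept their identifier. GENCODE 29 types 11019 rows as protein coding, 7 as another type, and 55 had no type. In every row the higher of the 2 group means was at least 0.5, which points to a filter on the group means before deposit, so genes under that level in both groups were not analysed here. The knockdown mean lay under 0.5 in 387 rows and the control mean in 106. Since 10981 identifiers ended in a low dash and a number, a form used by GENCODE releases mapped to GRCh37, while the annotation used here is on GRCh38, no coordinates are given. LINC01535, noncoding genes of nuclear RNAs and fibroblast markers were not analysed here. No 2 columns were identical.

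Rows of the 2 symbols held by more than 1 row were summed, and genes with a mean of at least 1 FPKM over the 6 libraries (10008) were kept. The values as deposited were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with group as the only term, empirical Bayes moderation with a mean-variance trend, two-sided p and Benjamini-Hochberg adjustment over all kept genes, at a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale unless FPKM levels are given, and understate the change of genes with low values. Because FPKM holds no counts, depth is unknown, no count test was run and no counting interval is given. An exact 0 in such a table can be a failed estimate, so genes are said to be listed at 0. Values of genes with near-identical copies, and of genes overlapped by readthrough transcripts, depend on how the authors' tools assigned shared fragments.

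Before the data were examined, 47 gene lists, the test, most of the other settings and the rule for the genes to name were fixed. Lists with at least 5 tested members (36) were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. The rule for named genes took the target, YBX3 and other single genes fixed by name. It also took the 10 genes with the largest and the 10 with the smallest log2 fold change among those past the threshold whose groups did not overlap, skipping pseudogenes, antisense genes and genes known only by a clone identifier. From each list called by camera, and from 9 lists chosen in advance whether called or not, it took up to 4 members with the largest absolute fold change among those past the threshold, or, where none passed, the 2 members with the smallest p. Members named beyond this rule, most of them where a count was 5 or fewer, were chosen after their values were seen. Some genes that the rule takes are not reported here.

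The other settings fixed in advance were the replicate number as a block, a pseudocount of 0.1, a filter at a mean of 0.1 and no filter, median scaling and quantile normalization of the libraries, limma without the trend, array weights, each of the 6 libraries left out in turn, camera with an estimated correlation, fry, and rows of shared symbols tested singly. Robust moderation, the removal of genes that jump in 1 library, and lists without shared members were added after the data were seen. The test was checked on simulated data with 10008 genes and 3 libraries per group, in which 50 genes each were changed by 0.5, 1, 2 and 3 on the log2 scale. It called 34%, 78%, 94% and 98% of them, with 9 unchanged genes among 161 calls, and camera called the shifted list and 0 of 40 unshifted lists. The noise was drawn for each gene separately, so the simulated genes were not correlated. The simulation therefore cannot show how often camera at the preset correlation calls unshifted lists whose members are correlated. Figures were drawn with matplotlib 3.10.9.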

Results

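Gene expression was measured by RNA-seq in T24 cells, an established human bladder cancer line, that stably carried a lentiviral control short hairpin RNA (shControl) or a short hairpin RNA directed against BLACAT3 (shBLACAT3), the long noncoding RNA of the gene LINC01535. Each group had 3 libraries, 6 in all, with 1 FPKM value (fragments per kilobase of transcript, scaled to the size of the library) per gene and library. The deposited table held 11081 gene rows, and 10008 genes with a mean of at least 1 FPKM over the 6 libraries were tested. The read depth behind the values is unknown, because FPKM values hold no read counts. The listed values summed to 220543, 220909 and 225122 FPKM in shControl replicates 1, 2 and 3 and to 211958, 215517 and 226953 in shBLACAT3 replicates 1, 2 and 3. Between 17 and 19 genes per shControl library and between 43 and 65 per shBLACAT3 library were listed at 0. The labels number the replicates but do not say whether they were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The targeted RNA itself was not analysed here, so the labels of the 2 groups were not checked against its level.

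The comparison asked which genes change when BLACAT3 is knocked down in these cells. Antiviral genes induced by interferon fell in shBLACAT3 cells, with 28 of 34 measured members of the interferon-stimulated list lower and 0 higher. CCL5, a chemokine that attracts T cells, was the gene with the lowest log2 fold change, at -6.75 (SE 0.12). Genes of class I antigen presentation (11 of 17 lower) and of the chemokine and cytokine list (9 of 14 lower) fell as well. The largest rise was smaller, that of ANKRD1, a transcriptional cofactor gene used as a readout of YAP activity, which went from 1.65 ± 0.12 to 16.3 ± 1.51 FPKM (SD, n = 3 per group).

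In all, 938 of the 10008 genes (9.37%) passed an adjusted p under 0.05 in limma, 257 higher and 681 lower in shBLACAT3 cells. The lower genes made up 72.6% of the calls, while the median log2 fold change of all tested genes was -0.0025. With a change of at least 2-fold on the log2(FPKM + 1) scale, 137 genes passed, 13 higher and 124 lower. This scale understates the change of genes with low values. The groups did not overlap in any of the 938 genes, and they did not overlap in 3279 genes (32.8%) of all tested, where chance gives 10% for 3 against 3. Across genes, Pearson's correlation of log2(FPKM + 1) was 0.982 to 0.983 between shControl libraries, 0.975 to 0.981 between shBLACAT3 libraries and 0.954 to 0.967 between the groups. The first principal component, with 49.5% of the variance, separated the groups, and the second, with 17.1%, spread the shBLACAT3 libraries. The count of calls rested on which libraries were kept. It was 357, 409 and 421 without shControl replicates 1, 2 and 3, 568 without shBLACAT3 replicate 1, 735 without shBLACAT3 replicate 2 and 1339 without shBLACAT3 replicate 3, and in this last setting 56.2% of the calls were lower. Of the 938 genes, 340 were also called without shControl replicate 1 and 800 without shBLACAT3 replicate 3. Of 86 genes past the threshold that a rule fixed in advance named, 61 kept their call whichever library was left out, and the other 25 lost it without at least 1 library: 23, 18 and 21 without shControl replicates 1, 2 and 3, and 12, 8 and 2 without shBLACAT3 replicates 1, 2 and 3.

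**Figure D1:**
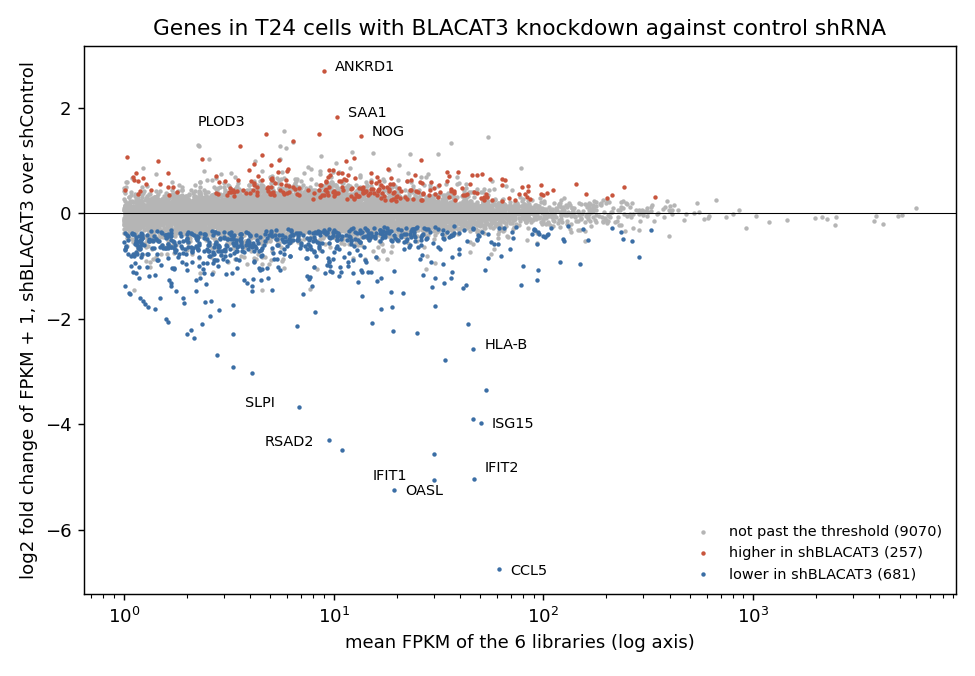
Log2 fold change of FPKM + 1 (shBLACAT3 over shControl, 3 libraries per group) against the mean FPKM of the 6 libraries on a log axis, 1 point per tested gene; blue points are the 681 genes that fell, red points the 257 that rose and grey points the genes not past an adjusted p of 0.05. CCL5 lies lowest at -6.75 and ANKRD1 highest at 2.70.

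Some single genes were examined because they had been fixed by name in advance. CYBA, the p22phox membrane subunit of the NADPH oxidase, fell from 48.8 ± 4.41 to 30.1 ± 3.77 FPKM (SD, n = 3), with an adjusted p of 0.013 in limma, and this call was lost without shControl replicate 1 (0.058) or 3 (0.053). RAC1, a small GTPase that takes part in oxidase assembly, stood at 169 ± 3.23 and 187 ± 4.71 FPKM and did not pass (adjusted p 0.13). YBX3, a cold shock domain protein that binds RNA and DNA, stood at 36.5 ± 3.95 FPKM in shControl and 37.5 ± 1.54 in shBLACAT3 cells, a log2 difference of 0.04 (SE 0.09, adjusted p 0.80) whose sign turned without shControl replicate 2 (-0.0074). Of the 4 measured cold shock domain genes, among them YBX1, YBX3 and CARHSP1, 0 passed in limma and 2 had an unadjusted p under 0.05.

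Besides CCL5, the genes with the largest fall included OASL, IFIT1, IFIT2, IFI44, RSAD2, ISG15 and IFIT3, all interferon-stimulated, and SLPI, a secreted inhibitor of leukocyte proteases. CCL5 stood at 123 ± 12.4 FPKM in shControl cells (SD, n = 3) and at a mean of 0.155 in shBLACAT3 cells, with 1 of the 3 libraries at 0. IFIT2 fell from 91.4 ± 2.90 to 1.80 ± 0.08 FPKM, and ISG15, a ubiquitin-like modifier, from 95.8 ± 10.0 to 5.13 ± 0.37. SLPI fell by 3.67 on the log2 scale (SE 0.22, adjusted p 0.00023). After ANKRD1, the largest rises were those of SAA1, an acute phase apolipoprotein, with a log2 fold change of 1.82 (SE 0.07), PLOD3, a collagen lysyl hydroxylase, with 1.51 (SE 0.08), F11R, a tight junction adhesion protein, with 1.5 (SE 0.09), and NOG, a secreted BMP antagonist, with 1.47 (SE 0.09). IGF2, DHRS3, CCDC25, TNFSF18 and RABIF rose by 1.05 to 1.38. Each of these genes still passed when any 1 library was left out. SAA1 has a near-identical neighbour, SAA2, and the split of reads between them is uncertain.

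**Figure D2:**
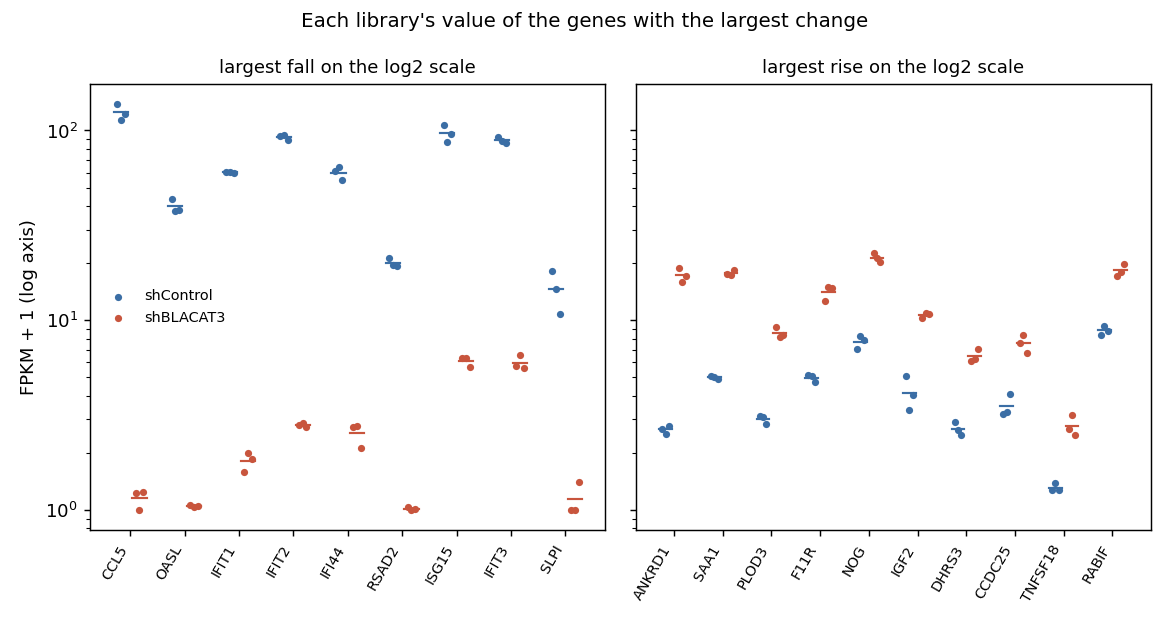
FPKM + 1 on a log axis in each library of 9 of the genes with the largest fall (left) and the 10 with the largest rise (right) among genes past the threshold; points are single libraries (blue shControl, red shBLACAT3, 3 each) and short lines are group means. The groups do not overlap in any of the genes shown, and CCL5 falls from a mean of 123 FPKM to 0.155.

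Of 36 gene lists with at least 5 tested members, limma's camera with a preset inter-gene correlation of 0.01 called 19, 14 lower and 5 higher. With a correlation estimated from these libraries it called 0 lists (10 of 36 at an unadjusted p under 0.05, smallest adjusted p 0.062). That setting also uses far fewer degrees of freedom, so its p-values do not measure correlation by itself. Limma's fry, which asks whether the members of a list move one way on balance, called 17 of the 19 and not the ATF4 and G2/M lists. The interferon-stimulated list had the lowest median log2 fold change, -1.36 (camera adjusted p 7.65e-34, and adjusted p = 0.062 with an estimated correlation). Adjusted over the list alone, 32 of its 34 members fell and 0 rose. Further members that fell were OAS2 and OAS1, which make the activator of RNase L, the RNA helicase sensors RIGI and IFIH1, and IFITM1, IFITM2 and IFITM3, near-identical membrane proteins whose reads cannot be cleanly split. STAT2 (3.35 and 3.0 FPKM, adjusted p 0.56), which carries the interferon signal to the nucleus, did not pass over all genes.

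The antigen presentation list fell with a median of -0.66 (camera adjusted p 1.83e-10, and adjusted p = 0.087 with an estimated correlation), and 14 of 17 members fell adjusted over the list alone. HLA-B, a class I heavy chain, fell from 80.2 ± 8.30 to 12.6 ± 0.64 FPKM (SD, n = 3), HLA-C by 1.49, the immunoproteasome subunit PSMB9 by 1.48 and HLA-F by 1.27 on the log2 scale. The HLA class I genes are similar and highly polymorphic, so their single values are uncertain. In the chemokine and cytokine list (median -1.02, camera adjusted p 3.32e-08, and adjusted p = 0.087 with an estimated correlation), 9 of 14 members fell and CXCL1 rose. Adjusted over the list alone, 11 fell and 2 rose. CXCL10 and CXCL11, chemokines induced by interferon, fell by 2.68 and 1.52 on the log2 scale, and CCL20 fell from 25.3 ± 1.12 to 5.35 ± 1.52 FPKM. Of 28 NF-kB targets 10 fell and 1, again CXCL1, rose, and adjusted over the list alone 14 fell and 1 rose (median -0.26, camera adjusted p 2.46e-06, and adjusted p = 0.075 with an estimated correlation). They included TNFAIP3, a feedback inhibitor of NF-kB, which fell by 1.88, the adhesion receptor ICAM1, which fell by 1.36, and the inhibitor NFKBIA, which fell by 1.23, next to CCL20. CXCL8, TNF and the NF-kB subunits RELA, NFKB1, NFKB2 and RELB did not pass over all genes.

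The epithelial list fell (median -0.31, camera adjusted p 0.00022, and adjusted p = 0.075 with an estimated correlation), with 5 of 13 members lower, namely MAL2, KRT8, KRT18, DSP and DSG2, and 0 higher. Adjusted over the list alone, 8 fell and 1 rose. MAL2, a protein of apical membrane traffic, fell by 2.37, and KRT8, a keratin of simple epithelia, went from 60.7 ± 4.78 to 22.1 ± 2.41 FPKM (SD, n = 3). The mesenchymal list was not called (median 0.12, camera adjusted p 0.60), with 3 of 12 members higher and 3 lower over all genes and adjusted over the list alone. S100A4 fell by 1.37 and SNAI2, a repressor of epithelial genes, by 0.78, and LOX by 0.41, while WNT5A rose with 1.0, CDH2, which encodes N-cadherin, with 0.45, and FN1 with 0.43 on the log2 scale. Without shControl replicate 1, the calls of KRT18, DSP and CDH2 were lost (adjusted p 0.092, 0.088 and 0.085). The calls of DSP and CDH2 were also lost without shControl replicate 2 or 3. That of KRT18 was also lost without shControl replicate 3 or shBLACAT3 replicate 1 or 2.

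Genes of the extracellular matrix and of angiogenesis fell more often than they rose. Of 18 collagens and matrix proteins 8 fell and FN1, fibronectin, rose (adjusted over the list alone 11 fell and 1 rose; median -0.39, camera adjusted p 0.0018, and adjusted p = 0.29 with an estimated correlation). COL6A1 and COL6A2, chains of collagen VI, fell by 1.47 and 1.0, and LAMB3, a laminin chain, by 1.12. Of 19 matrix proteases and inhibitors 9 fell and ADAMTS1 rose (adjusted over the list alone 10 fell and 3 rose; median -0.29, camera adjusted p 0.0067, and adjusted p = 0.34 with an estimated correlation). SERPINE2, an inhibitor of serine proteases, fell by 1.78 and the urokinase gene PLAU by 0.95, from 197 ± 6.93 to 101 ± 1.83 FPKM (SD, n = 3). Of 30 angiogenic factors and receptors 13 fell and 2, THBS1 and EDN1, rose (adjusted over the list alone 14 fell and 3 rose; median -0.22, camera adjusted p 0.00022, and adjusted p = 0.21 with an estimated correlation). FGF2, a fibroblast growth factor, fell by 1.30 on the log2 scale and VEGFC by 0.86, while VEGFA had a log2 fold change of -0.10 and did not pass. PLAU is a member of both of these lists. Camera did not call the integrins (median -0.18, camera adjusted p 0.29), while fry called them for a common direction (fry adjusted p 0.039). Among the 12 integrins ITGA5, ITGB4, ITGB3 and ITGA6 were lower and ITGB1 higher, and 5 were lower and 2 higher adjusted over the list alone.

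Among stress and signalling lists, 9 of 26 genes of the unfolded protein response fell and ATF4 rose (adjusted over the list alone 12 fell and 1 rose; median -0.30, camera adjusted p 2.67e-06, and adjusted p = 0.062 with an estimated correlation). The endoplasmic reticulum chaperone HSPA5 fell from 314 ± 3.13 to 217 ± 4.71 FPKM (SD, n = 3) and the disulfide isomerase PDIA4 by 0.50 on the log2 scale. Of 23 hypoxia targets 8 fell and STC2 rose (adjusted over the list alone 13 fell and 2 rose; median -0.25, camera adjusted p 0.00047, and adjusted p = 0.23 with an estimated correlation), among them BNIP3, a mitophagy receptor, by 0.79. The 23 glycolysis genes (median -0.28, camera adjusted p 0.00041, and adjusted p = 0.34 with an estimated correlation) held 4 that fell, PFKFB4, HK2, LDHA and PGAM1, and 1 that rose, PFKFB2, with 0.57. Adjusted over the list alone, 12 fell and 1 rose. PFKFB4 and HK2 are also among the hypoxia targets that fell. Of 24 immediate early genes 8 fell and 0 rose (adjusted over the list alone 9 fell; median -0.21, camera adjusted p 0.0025, and adjusted p = 0.45 with an estimated correlation), and the transcription factor genes KLF4 and JUNB fell by 1.51 and 1.18 on the log2 scale. SPRED3, DUSP4 and FOSL1 fell among 17 genes of MAPK feedback (adjusted over the list alone 6 fell and 1 rose; median -0.10, camera adjusted p 0.020, and adjusted p = 0.40 with an estimated correlation). These last 2 lists lost their camera call without shBLACAT3 replicate 2 (adjusted p 0.064 and 0.069). Of the list of 16 replication-dependent histone genes 2, H4C3 among them, fell over all genes and adjusted over the list alone (median -0.30, camera adjusted p 0.0051, and adjusted p = 0.14 with an estimated correlation). Without shControl replicate 1 the calls of ATF4, HK2, PFKFB4, LDHA, SPRED3, FOSL1 and H4C3 were lost, with adjusted p from 0.058 to 0.14, and those of LDHA and FOSL1 were also lost under quantile normalization. All of these calls but that of ATF4 were also lost without another library. Those of LDHA and H4C3 were lost when any of 5 libraries was left out.

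**Figure D3:**
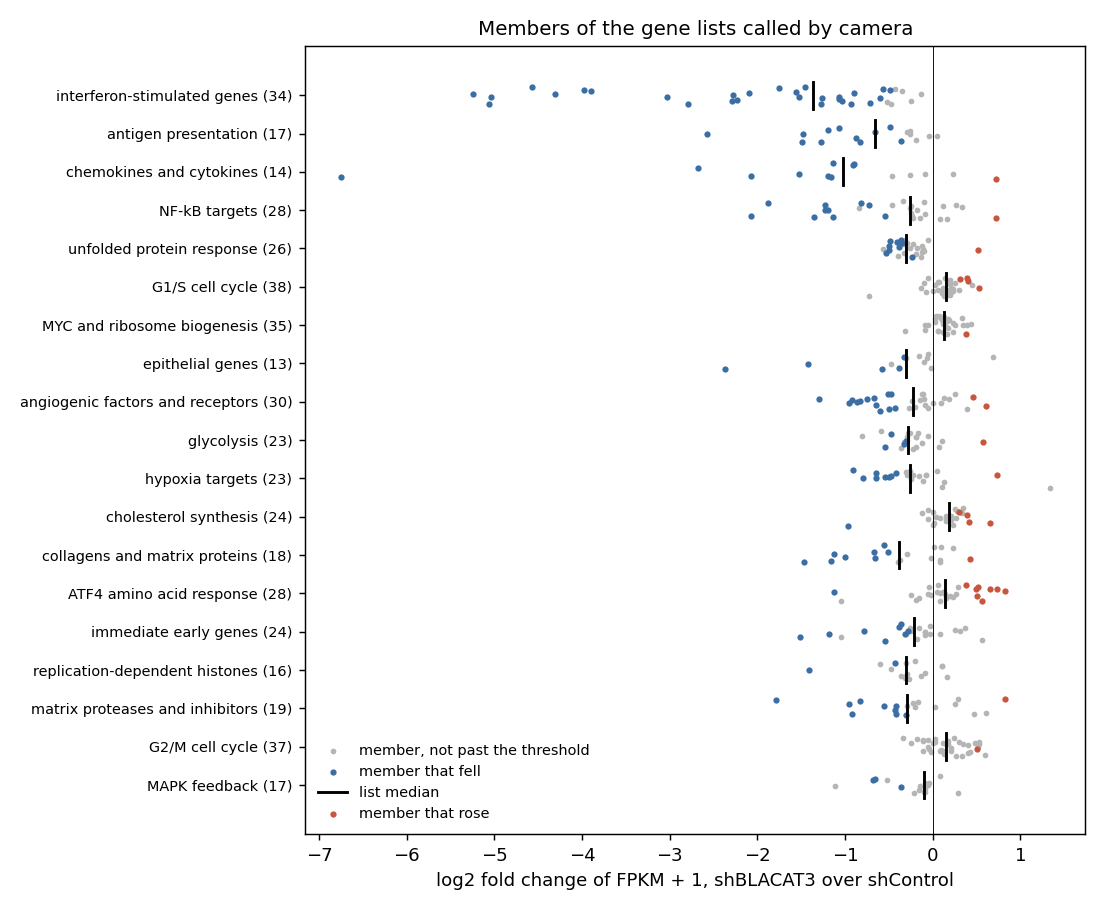
Log2 fold change of FPKM + 1 (shBLACAT3 over shControl, 3 libraries per group) of each member of the 19 gene lists that camera called with a preset correlation, 1 point per gene and 1 line of points per list, with the number of tested members in brackets; blue members fell, red members rose, grey members did not pass an adjusted p of 0.05, and black bars are list medians. The interferon-stimulated list has its median at -1.36, and the medians of the other 18 lists lie between -1.02 and 0.18.

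Higher lists moved by small amounts. In the G1/S list, genes of DNA replication and its control, 33 of 38 members had a higher mean, but only RFC4, GINS2, CLSPN and TYMS passed over all genes, 5 members rose adjusted over the list alone and 0 fell either way (median 0.16, camera adjusted p 1.53e-05, and adjusted p = 0.062 with an estimated correlation). RFC4, a subunit of the clamp loader, rose from 13.6 ± 0.15 to 20.1 ± 0.50 FPKM (SD, n = 3). In the G2/M list PLK1, a mitotic kinase, rose and 0 of 37 fell, also adjusted over the list alone (median 0.16, camera adjusted p 0.0067, and adjusted p = 0.40 with an estimated correlation). In the list of MYC and ribosome biogenesis RRS1 rose and 0 of 35 fell, also adjusted over the list alone (median 0.13, camera adjusted p 4.87e-05, and adjusted p = 0.062 with an estimated correlation). Of 24 cholesterol synthesis genes INSIG1, ACAT2, IDI1 and SQLE rose and HMGCS1 fell (adjusted over the list alone 8 rose and 1 fell; median 0.18, camera adjusted p 0.00061, and adjusted p = 0.075 with an estimated correlation). INSIG1, which retains the sterol sensor in the endoplasmic reticulum, rose with 0.65, and HMGCS1, the synthase that makes HMG-CoA, fell by 0.97. Of 28 genes of the ATF4 amino acid response 8 rose and WARS1 fell (adjusted over the list alone 10 rose and 3 fell; median 0.14, camera adjusted p 0.0018, and adjusted p = 0.40 with an estimated correlation). SLC7A11, the cystine transporter, rose with 0.82 (SE 0.19) and STC2 with 0.73 (SE 0.06), and WARS1, the tryptophan tRNA synthetase, which interferon also induces, fell by 1.12. Without shControl replicate 1 the calls of GINS2, CLSPN, TYMS, PLK1, RRS1, ACAT2, IDI1, ATF4 and SLC7A11 were lost, with adjusted p from 0.058 to 0.15. All of these calls but that of ATF4 were also lost without another library. Those of CLSPN, TYMS and SLC7A11 were lost when any of 5 libraries was left out, and those of IDI1 and PLK1 with any of 4.

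Camera with the preset correlation did not call the other lists. Fry did call the TGF-beta (adjusted p 0.0029), apoptosis (0.014), p53 (0.016) and lysosome and autophagy (0.043) lists for a common direction. Of 27 apoptosis regulators 5 fell, among them PMAIP1, BBC3, MCL1 and FADD, also adjusted over the list alone (median -0.14, camera adjusted p 0.053), and camera called the list without shControl replicate 3 (0.034) or shBLACAT3 replicate 3 (0.029). Of 26 p53 targets FAS, BBC3, BTG2, TNFRSF10B and TRIAP1 fell and GDF15, a stress-induced cytokine, rose from 25.3 ± 2.24 to 44.5 ± 4.05 FPKM (SD, n = 3; camera adjusted p 0.17). Adjusted over the list alone, 6 p53 targets fell and 1 rose. FAS lost its call without shControl replicate 1 (0.14), 2 or 3 or shBLACAT3 replicate 3. BTG2 lost its call without shBLACAT3 replicate 1 (0.076) or 2 (0.069) and under quantile normalization. Of 18 TGF-beta targets 6 fell, and PMEPA1 and TGFB2 rose (6 fell and 4 rose adjusted over the list alone; camera adjusted p 0.17). Of 23 YAP targets ANKRD1 and TGFB2 rose and IGFBP3, NT5E and NUAK2 fell, also adjusted over the list alone (camera adjusted p 0.56). Of 32 lysosome and autophagy genes 4 fell, among them CTSL and GABARAPL1 (4 adjusted over the list alone; camera adjusted p 0.29). CPT1A and ACSS2 fell and FABP5 rose among 24 genes of fatty acid synthesis and storage (the same numbers adjusted over the list alone; camera adjusted p 0.47). ABCC3 and UGDH fell and SLC7A11 rose among 22 NRF2 targets (2 and 1 adjusted over the list alone; camera adjusted p 0.79). HSPB1 and FKBP4 fell and CHORDC1 rose among 22 heat shock genes (2 and 1 adjusted over the list alone; camera adjusted p 0.81). For the NRF2, heat shock and m6A lists the median, the mean and the test differed in sign. IGF2BP3 fell among 20 genes of the m6A machinery (1 adjusted over the list alone; camera adjusted p 0.77), CYP2J2 among 6 luminal urothelial genes (2 adjusted over the list alone; camera adjusted p 0.66), and 1 of 14 reference genes fell (1 adjusted over the list alone; camera adjusted p 0.59).

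NDUFS3 and ATP5PB rose among 40 genes of oxidative phosphorylation (1 adjusted over the list alone; camera adjusted p 0.66), and RPL6 among 74 ribosomal protein genes (0 adjusted over the list alone; camera adjusted p 0.084). Of the 13 mitochondrial transcripts (camera adjusted p 0.54) and of the 10 zinc finger genes of chromosome 19q13, the region of LINC01535 (camera adjusted p 0.17), 0 passed in limma, over all genes or adjusted over the list alone, and 1 of each had an unadjusted p under 0.05. Camera called the ribosomal list higher without shControl replicate 3 (0.013), shBLACAT3 replicate 1 (0.00013) or shBLACAT3 replicate 2 (0.042), and the oxidative phosphorylation and mitochondrial lists lower without shBLACAT3 replicate 3 (0.039 and 0.00081). Lists with fewer than 5 tested members were only described. Of the basal squamous list, CD44, ITGA6 and LAMB3 fell among 4 tested genes, and KRT6A, KRT17 and PI3 lay under the level tested. Of markers of other cell types, the erythroid genes HBA1, HBA2 and HBB, the first 2 of which are near-identical, stood at 8.33, 8.14 and 10.8 FPKM in shControl and 7.73, 7.15 and 10.9 in shBLACAT3 cells, and none of them passed. PAX2, a marker of HEK293 packaging cells, stood at 3.69 and 3.66 FPKM, the endothelial marker ESAM fell from 3.57 to 1.76 FPKM (adjusted p 0.015 in limma), and the leukocyte marker CD68 stood at 1.04 and 0.372 FPKM, under the level tested. These were the only markers of their lists with a row, 1 of 10 HEK293, 1 of 10 endothelial and 1 of 13 leukocyte markers. Of the erythroid and serum list 3 of 9 had a row. Fibroblast markers and the list of RNA polymerase III transcripts and abundant nuclear noncoding RNAs were not analysed here.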

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

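Robust moderation, the removal of jumping genes and the lists without shared members were tried after the data were seen; the other settings were fixed before. Apart from the values named here, the counts of genes, of genes changed at least 2-fold and of called lists stayed within 1.5 times 938, 137 and 19. With the replicate block the count of genes was 612, 580 of them among the 938, with 10 of the named genes no longer past the threshold, and it was 135 genes at least 2-fold and 19 lists. The numbers were not taken to pair the samples, because the deviations of same-numbered libraries correlated at 0.10, 0.117 and 0.0896 across genes, although each library correlated best with its own number. A pseudocount of 0.1 gave 227 genes at least 2-fold, since low values then spread further. Without 1 library the counts ranged from 357 to 1339 genes, 123 to 155 genes at least 2-fold and 18 to 22 lists, with fewer libraries in each fit. Camera with an estimated correlation called 0 lists (10 at an unadjusted p under 0.05). In some of the 19 lists the estimate lay below the preset 0.01, as in the unfolded protein response (-0.014) and G1/S (-0.0037) lists. For such lists a higher correlation cannot be what ended the call. With an estimate, camera also refers its statistic to the residual degrees of freedom of the 6 libraries. This step raises p whatever the correlation, so these p-values do not measure the effect of correlation by itself. Fry called 22 for a common direction and 33 for either direction, with 17 of the 19 among the 22. YBX3 ranged from -0.0074 (without shControl replicate 2, reversed) to 0.13, never past the threshold; the cause was not tested. Over the settings fixed in advance other than estimated correlations and fry, 1121 named-gene values kept direction and call and 101 lost the call. Of the list values 490 stayed called or stayed not called, 2 lost the call and 12 gained it. A list that turned direction while called in neither fit was counted among the 490. The cause of these changes was not tested. Of 86 named genes past the threshold, 61 stayed past it without any 1 library. A filter at 0.1 and no filter kept the same genes and are 1 setting (1186 calls). A count test on recovered reads and the alternatives on the target were not run. Depth is unknown, so the limits it sets could not be given.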

Other observations

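The genes of the interferon pathway, the search for genes near 0 in 1 group, the tests of the interferon state of the control line and of low-level noise, and the lists without shared members were chosen after the result was seen; the other tests were set before. Beyond the fixed lists, the ligands of the interferon response were themselves lower in shBLACAT3 cells. IFNB1, the gene of interferon beta, fell from 2.54, 2.31 and 2.56 FPKM in the shControl libraries to 0, 0.145 and 0 (adjusted p 0.00011 in limma), and the type III interferon gene IFNL1 from 6.41, 7.23 and 6.18 FPKM to being listed at 0 in all 3 shBLACAT3 libraries. IFNL2 and IFNL3, which are near-identical and hard to tell apart, passed as well, so 4 of 4 tested ligands fell. Of 6 tested genes of nucleic acid sensing, among them the RNA-editing gene ADAR, 3 fell. RIGI fell from 47.6 ± 3.02 to 13.5 ± 1.03 FPKM (SD, n = 3), IFIH1 from 32.2 ± 0.93 to 6.07 ± 0.59, and TLR3 by 0.46 on the log2 scale. CGAS stood at 17.9 and 18.8 FPKM and did not pass. Of 7 adaptors and kinases MYD88, which serves Toll-like receptors, rose from 3.30 ± 0.14 to 7.67 ± 0.51 FPKM and 0 fell. Of 11 transcription factors IRF1 and IRF7 fell, and of 8 receptor chains and kinases IFNLR1, a chain of the type III interferon receptor, fell. RIGI, IFIH1 and IRF7 are members of the interferon-stimulated list and IRF1 of the NF-kB list, so their falls were already counted there.

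A small set of genes was near 0 after knockdown. With a mean of at least 2 FPKM in shControl cells and under 0.1 FPKM in every shBLACAT3 library there were 12 genes, and there were 0 in the opposite direction. They include OASL, RSAD2, CXCL10, IFNL1, IFNL2 and IFNL3, and outside the interferon group MAL2, the matrix proteoglycan gene SPOCK1 (control mean 3.99 FPKM) and the protease inhibitor gene SERPINA1 (control mean 2.77 FPKM). ARPIN-AP3S2, a readthrough gene, meets the bounds through shControl replicate 3 alone (7.92 FPKM). PI3, another protease inhibitor, stood at 1.32, 1.2 and 2.13 FPKM in shControl and was listed at 0 in all 3 shBLACAT3 libraries, too low on average to be tested.

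The fall of the interferon-stimulated genes stayed at a list median of -1.30 under quantile normalization and -1.36 under median scaling. The median log2 fold change of all tested genes was -0.0025 before any scaling, so the outcome under median scaling was nearly fixed in advance. That median near 0 itself argues against a difference in scaling between the libraries as the source of this fall. It was -1.26 or lower whichever library was left out, so no single library carries it. What stays open is whether loss of BLACAT3 lowered interferon signalling or whether the shControl cells were in an interferon-active state of their own. IFNB1 had a mean of 2.47 FPKM in shControl and 0.0483 in shBLACAT3 cells, but no untransduced cells and no further control hairpin are among the 6 libraries, so these explanations cannot be told apart. A biological effect of the hairpin on interferon production therefore remains a hypothesis, and a hairpin's unintended targets were not tested.

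More genes fell than rose, 72.6% of the calls. Lower calls still made up 64.3% under quantile normalization and 70.1% under median scaling, which argues against scaling as the whole cause, although scaling may account for part of it. Outside the interferon, antigen presentation, chemokine and NF-kB lists 70.9% of 881 calls were lower, so the members of these lists alone do not make up the excess. They held too few of the 938 calls to move the share much, so this outcome was nearly fixed in advance. Called genes such as IFNB1, IFNL1 and WARS1 stay among the 881, so the part of a wider interferon response was not tested. Among 390 called genes with a mean of at least 10 FPKM the share was 61.3% (exact 95% interval 56.2 to 66.1%). This interval treats the genes as independent draws, although all were measured in the same 6 libraries, so it does not measure the spread between libraries. A part played by low values cannot be told apart from a real excess of falls. Without shBLACAT3 replicate 3 there were 753 lower and 586 higher calls, so the share of 56.2% came with more calls in both directions.

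In 106 genes 1 library of a group differed by over 4-fold from both others of its group. For example, TXNDC5, an endoplasmic reticulum disulfide isomerase, read 55.4, 4.20 and 3.87 FPKM in shControl and 52.9, 3.12 and 4.0 in shBLACAT3 replicates 1, 2 and 3, while its readthrough neighbour BLOC1S5-TXNDC5 read 0.690, 67.8 and 74.2 and then 0.489, 68.9 and 76.1. In 24 genes a library jumped in both groups, against a mean of 0.49 in 10000 draws matched on level (p 1e-04, the smallest the draws can give), consistent with an estimate that is unstable for the gene itself, such as fragments moved between overlapping genes. The share of jumping genes below the median level of all genes was 68.9%, which leaves open a part played by low-level noise. Of the 95 jumping genes that were tested limma called 0, so such a gene may hide a change.

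The NF-kB list shares 5 tested members with the chemokine list and 0 with the interferon and antigen presentation lists. Without these 5 genes camera with the preset correlation still called the list, with a median of -0.25 over 23 members and an adjusted p of 8.48e-06, and adjusted p = 0.087 with an estimated correlation. Without the 4 members that the angiogenic list shares with the matrix protease list, its 26 others had a median of -0.13 and a camera adjusted p of 0.0093, and adjusted p = 0.31 with an estimated correlation. At the preset correlation neither call rested on the shared members alone. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. In 1 of the 10 splits, the real one, the count of genes reached 938, against at most 7 in the others. The count of genes changed at least 2-fold reached 137 in 1 of 10 splits, with at most 6 in the others, and that of called lists 19 in 1 of 10, with at most 16. In every other split the difference between the hairpins adds to the spread within the groups. Low counts of genes there were therefore likely in advance and lend the real counts no support. The high count of lists in other splits shows that camera with a preset correlation also calls lists when each group mixes both hairpins, although such splits keep part of the real difference, and 18 of the 19 lists, all but the epithelial list, were called in at least 1 of the 9 other splits. In 17 of the 19 lists the real median was larger in size than in any other split. This was likely in advance, because the lists were those called in the real split and every other split dilutes the difference. It therefore lends the lists no further support.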
